A study of Mus musculus with 12 samples.

How the data were processed

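The deposited files hold integer gene counts, 1 file per library, and these counts were used without change. Per the file headers, the authors made the counts with featureCounts 1.5.2 on the Ensembl annotation of GRCm38, reverse-stranded, at exons summed by gene, with reads allowed to overlap several genes and assigned to the largest overlap, chimeric fragments left out and multi-mapping reads counted at every alignment. Per the submitters' processing notes, reads were converted with bcl2fastq 2.18.0.12, aligned to mm10 with STAR 2.5.2b and counted with Subread 1.5.2. Per the labels' protocols, total RNA was taken with a NucleoSpin kit and libraries were made with the TruSeq Stranded mRNA kit. Trimming, read length and any removal of duplicates are not given in the sources used here. Reads themselves were not used here. Values of paralogs and pseudogenes are uncertain, because a read that aligns to several places was counted at each. Of 49671 genes in the files, 49326 were matched to a symbol and 345 were not.

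Differential expression was tested with edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr (17977), TMM scaling, a design with 1 mean for each of the 4 groups (8 residual degrees of freedom), glmQLFit and the quasi-likelihood F-test, two-sided. P-values were adjusted by Benjamini-Hochberg over all tested genes within a comparison, and a gene passed below 0.05. The comparisons were mutant against WT in nTregs, the same in iTregs, the difference between these 2 effects, and WT iTregs against WT nTregs. Log2 fold changes are the fitted values of edgeR with its default prior count, and the SE comes from the F statistic of the same fit. CPM values are scaled by the TMM library sizes and given as mean ± SD over 3 libraries. Where a group had no count, the fold is a lower bound against 3 counts over the group, which covers counting error only.

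The design, the gene lists, the named-gene rule and the alternatives were fixed before the data were examined, except where said. The 24 lists were glutathione, NRF2 and thioredoxin, serine and one-carbon metabolism, ATF4 response, glycolysis and hypoxia, sterol and fatty acid synthesis, nuclear oxidative phosphorylation, mitochondrially encoded, Treg core, effector Treg, resting and lymphoid homing, T cell effector and cytokine, proliferation, interferon response, p53 response, metallothionein and metal, MYC and ribosome biogenesis, unfolded protein, immediate early and handling, and markers of B cells, plasma cells, myeloid cells, CD8 and NK cells and erythroid cells. The lists were written from general knowledge and some share genes. For each, the members past the threshold were counted, over all genes and adjusted over the list alone, and lists of 5 or more tested members were tested with camera on log CPM with a prior count of 2 (limma 3.58.1, preset correlation 0.01), adjusted over the lists within a comparison. Camera was also run with the correlation estimated from the data.

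Genes were named by rule. Gclc came first, and Gclm, Gss, Foxp3, Slc1a4, Slc1a5, Phgdh, Psat1, Shmt1, Shmt2 and Mthfd2 were named whatever their values. For each list, up to 4 members with the smallest adjusted p that passed were open to be named, or 1 where none passed. For each comparison and direction the 8 largest log2 fold changes were named (5 for the difference) among genes that passed with a mean of at least 5 CPM in a compared group. For these, every library of one group lay beyond every library of the other, which chance gives for 10% of genes with 3 libraries against 3 (this was not asked of the difference). Predicted genes without a name and pseudogenes were passed over. Some genes open to be named are not reported here.

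The alternatives were RLE scaling, scaling by library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, the compared libraries alone, the replicate number as a block, and each library left out in turn. For the lists they were camera with an estimated correlation, fry, library size alone and each library left out. Protein-coding genes alone, the list counts with each library left out, and list tests of the difference on genes with a group mean of at least 1 CPM in both cell types, were chosen after seeing the data. Intervals of medians come from 10000 bootstrap resamples of genes (95%).

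The fit was checked on simulated counts with the dispersions of these libraries and 200 genes changed, 50 at each of 4 fold sizes. The real effect was removed first, and each gene had a single dispersion for all libraries. The many real changes and the unequal noise of the libraries were therefore not simulated. A single simulation was run at the start and 2 were added after its nTreg comparison gave 11.3% false calls. Over the 3 simulations false calls were 3.4% to 11.3% of calls for nTregs (6.5% pooled), 2.8% to 4.5% for iTregs, 1.9% to 7.3% for the difference and 2.8% to 5.4% for WT iTregs against nTregs. Genes changed 2-fold were found in 76%, 65.3%, 54% and 74% of cases, and genes changed 1.5-fold in 44.7%, 38.7%, 18.7% and 41.3%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.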

Results

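RNA was sequenced from regulatory T cells (Tregs), the CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3, of 8-week-old C57BL/6 mice. The mice were wild type (WT) or carried a mutation of Gclc, which encodes the catalytic subunit of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis. Tregs isolated directly from the animals (nTregs) and Tregs induced in culture from naive CD4 T cells (iTregs) were profiled, with 3 libraries in each of the 4 groups and 12 in all. The deposited gene counts summed to between 28.7e6 and 39.9e6 per library. Nothing beyond the labels says whether libraries of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. By a chi-square test, libraries of a group differed by 4.49 to 52.16 times the counting noise per degree of freedom.

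Gclc (ENSMUSG00000032350; GRCm38, chromosome 9, 77754535 to 77794485, plus strand) was lower in every mutant library than in every WT library of the same cell type. In nTregs it was at 78.7, 79 and 70.8 CPM (counts scaled to the TMM library size) in WT and at 45.8, 41.7 and 43.2 CPM in the mutant. This was a log2 fold change of -0.81 ± 0.07 (SE, n = 3 against 3, adjusted p = 7.03e-05). In iTregs it was at 56.5, 53.2 and 51.9 CPM in WT and at 18.8, 21 and 19 CPM in the mutant. This was a log2 fold change of -1.46 ± 0.08 (adjusted p = 1.64e-06). Which exons the mutation removes was not analysed here, so reads from the rest of a mutated transcript may remain in these values.

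The comparison of mutant with WT nTregs asks how loss of Gclc changes the transcriptome of Tregs in the animal. Foxp3 (ENSMUSG00000039521; chromosome X) fell from 578 ± 28.5 to 178 ± 41.2 CPM (SD, n = 3 each), a log2 fold change of -1.70 ± 0.15 (adjusted p = 7.03e-05). Genes of serine and one-carbon metabolism rose. Phgdh and Psat1, which make serine from a glycolytic intermediate, rose by 0.81 ± 0.07 and 1.03 ± 0.09 on the log2 scale (adjusted p = 5.57e-05 and 6.56e-05). Shmt1, Shmt2 and Mthfd2, which pass the carbon of serine to folate, rose by 0.95 ± 0.13, 0.83 ± 0.11 and 0.93 ± 0.09, and Tyms, which uses that carbon to make thymidylate, by 1.35 ± 0.17. The neutral amino acid transporter Slc1a4 rose from 1.01 ± 0.07 to 3.79 ± 1.04 CPM (log2 fold change 1.91 ± 0.24, adjusted p = 0.000273), while its relative Slc1a5 did not pass the test (-0.15 ± 0.07, adjusted p = 0.111). Of 34 measured genes of the serine and one-carbon list, 19 rose and 1 fell (19 and 2 adjusted over the list alone). The list ranked high against all other genes (camera, adjusted p = 0.000314), a call lost with a correlation between its genes taken from the data (adjusted p = 0.399 with an estimated correlation).

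Targets of ATF4, the transcription factor of the amino acid and stress response, moved the same way in nTregs. Asns, which makes asparagine, rose from 2.27 ± 0.58 to 19.3 ± 2.01 CPM (log2 fold change 3.09 ± 0.16, adjusted p = 2.07e-06). Of 37 measured ATF4-response genes, some of which are also on the serine list, 24 rose and 1 fell (27 and 1 adjusted over the list alone; camera, adjusted p = 1.54e-08, and adjusted p = 0.399 with an estimated correlation). Among glutathione genes, Gss, which completes glutathione, rose by 0.60 ± 0.13 (adjusted p = 0.00427) and Gclm, the regulatory partner of Gclc, by 0.49 ± 0.14 (adjusted p = 0.0175). The Gclm call was lost without nTreg WT library 1 (adjusted p = 0.0764) or 2 (adjusted p = 0.0723). Of the 35 measured glutathione genes, 15 rose and 3 fell (15 and 4 adjusted over the list alone; camera, adjusted p = 0.0787). The antioxidant genes Sod1 and Txn1 rose by 0.58 ± 0.07 and 1.23 ± 0.16. Of 35 NRF2 and thioredoxin genes 15 rose and 2 fell, the same counts when adjusted over the list alone (camera, adjusted p = 0.0029, and adjusted p = 0.52 with an estimated correlation). With each library left out in turn, the genes that rose were 19 to 26 of the ATF4 response, 17 to 20 of the serine list, 10 to 16 of NRF2 and 8 (without nTreg WT library 1) to 17 of glutathione.

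**Figure D1:**
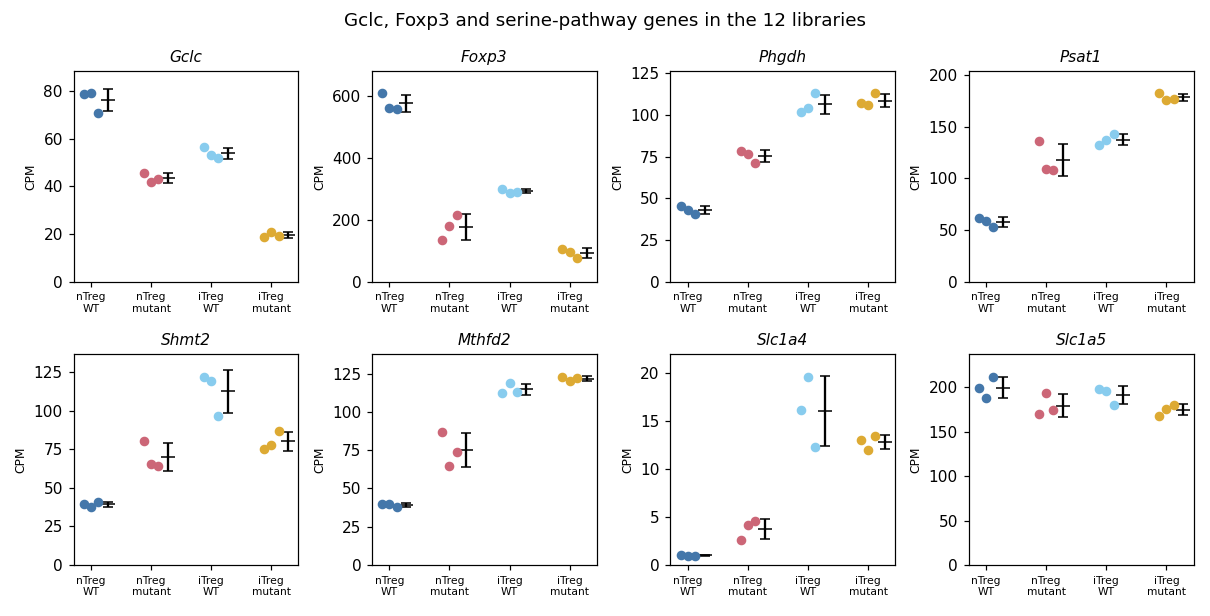
CPM (linear axes from 0) of Gclc, Foxp3 and 6 genes of serine synthesis, use or transport, 1 point per library in each of the 4 groups; the bar beside each group is the mean with its SD. Foxp3 was lower in all mutant libraries of both cell types, and Phgdh was at 43.1 CPM in WT and 75.6 CPM in mutant nTregs against 107 and 109 CPM in iTregs.

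All 47 measured proliferation genes rose in mutant nTregs (also 47 adjusted over the list alone), with a median log2 fold change of 1.6 (camera, adjusted p = 1.19e-23, and adjusted p = 0.449 with an estimated correlation). E2f1, a driver of S phase entry, rose by 1.41 ± 0.13, Uhrf1, which maintains DNA methylation at replication, by 1.55 ± 0.16, and Mcm3, of the replicative helicase, by 1.24 ± 0.15. Of 76 nuclear genes of oxidative phosphorylation, 48 rose and 0 fell (57 and 0 adjusted over the list alone; camera, adjusted p = 1.39e-10, and adjusted p = 0.579 with an estimated correlation). Among them were Cox6a1 of cytochrome c oxidase up by 0.54 ± 0.08 and Atp5g1 of ATP synthase up by 0.54 ± 0.08. Of the 13 mitochondrially encoded genes 1, mt-Nd2, rose (0.59 ± 0.13), also when adjusted over the list alone. Of 35 MYC and ribosome biogenesis genes, 19 rose and 0 fell (23 and 0 adjusted over the list alone; camera, adjusted p = 1.1e-05, and adjusted p = 0.579 with an estimated correlation). The polyamine enzymes Srm and Odc1 rose by 0.67 ± 0.12 and 1.08 ± 0.20. Among 36 glycolysis and hypoxia genes 15 rose and 5 fell (18 and 6 adjusted over the list alone; camera, adjusted p = 0.0787). Hk2, which phosphorylates glucose, rose by 1.5 ± 0.22. Pdk1, which restrains pyruvate oxidation in mitochondria, fell by 0.77 and the collagen hydroxylase P4ha1 fell by 1. Of 33 sterol and fatty acid genes, 5 rose and 3 fell, as they did adjusted over the list alone (camera, adjusted p = 0.437). Over the libraries left out in turn, 47 proliferation genes rose every time, 32 to 49 of oxidative phosphorylation, 12 (without nTreg WT library 2 or 3) to 22 of MYC and ribosome biogenesis, 12 to 16 of glycolysis and 3 (without nTreg WT library 1 or 3) to 6 of sterol synthesis.

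Apart from Foxp3, the Treg core genes did not move together in nTregs. Of 30 measured, Foxp3 included, 5 rose and 3 fell (3 and 3 adjusted over the list alone; camera, adjusted p = 0.811). The checkpoint receptor Lag3 rose by 0.88 ± 0.15 and the G protein regulator Rgs1 by 0.80 ± 0.16, and the vesicle docking gene Sytl2 fell by 1.24. Of 22 genes of resting and lymph node homing T cells, 15 fell and 1 rose, also adjusted over the list alone (camera, adjusted p = 7.56e-07, and adjusted p = 0.445 with an estimated correlation). Klf3 fell by 1.18 and Foxo1 and Lef1, transcription factors of quiescent T cells, fell by 0.80 and 0.64. Of 36 effector Treg genes 14 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.0787). The transcription factor Bhlhe40 rose by 2.10 ± 0.32 and the lectin Lgals1 by 1.40 ± 0.25. Of 40 T cell cytokine and effector genes, 21 rose and 3 fell (22 and 4 adjusted over the list alone; camera, adjusted p = 0.0029, and adjusted p = 0.579 with an estimated correlation). Their median log2 fold change was 1.36, and 0.81 without nTreg mutant library 1, where 9 of 10 CD8 and NK markers were also the highest of the 3 mutant libraries. The cytokine gene Il21 rose from 1.29 ± 0.70 to 7.12 ± 0.82 CPM and the receptor gene Il18r1 by 1 ± 0.14 on the log2 scale. Leaving out 1 library at a time, 2 (without any of 4 single libraries) to 7 Treg core, 12 to 16 effector Treg and 13 (without nTreg WT library 3) to 21 cytokine and effector genes rose, and 12 to 16 resting genes fell.

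Of 49 interferon-response genes in nTregs 12 fell and 3 rose, also adjusted over the list alone (camera, adjusted p = 0.165). The neighbouring family members Ifi213, Ifi206 and Ifi208, which multi-mapping reads can blur, fell by 1.16, 0.95 and 0.95. Of 27 p53-response genes 13 rose and 5 fell, also adjusted over the list alone (camera, adjusted p = 0.0971). The cell cycle inhibitor Cdkn1a went from 2.13 ± 0.23 to 22.4 ± 6.13 CPM. Sesn1, a nutrient-sensing inhibitor of growth signalling, changed by -1.56 ± 0.17. The 16 metallothionein and metal genes split into 4 higher and 3 lower (4 and 3 adjusted over the list alone; camera, adjusted p = 0.437). The metal-binding Mt1 rose from 0.304 ± 0.06 to 2.68 ± 1.43 CPM. Of 25 unfolded-protein genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera, adjusted p = 0.24). Of 28 immediate early and handling genes 3 rose and 7 fell (3 and 7 adjusted over the list alone; camera, adjusted p = 0.154). The RNA-decay factor Zfp36 changed by -0.92 ± 0.11. Over the libraries left out in turn, 9 to 13 interferon-response genes fell and 2 to 7 (without nTreg mutant library 2) rose. The genes that rose were then 7 (without nTreg WT library 3) to 15 of p53 and 2 (without nTreg WT library 2 or 3) to 11 of unfolded protein, and metal genes that fell 1 (without nTreg WT library 2) to 3.

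**Figure D2:**
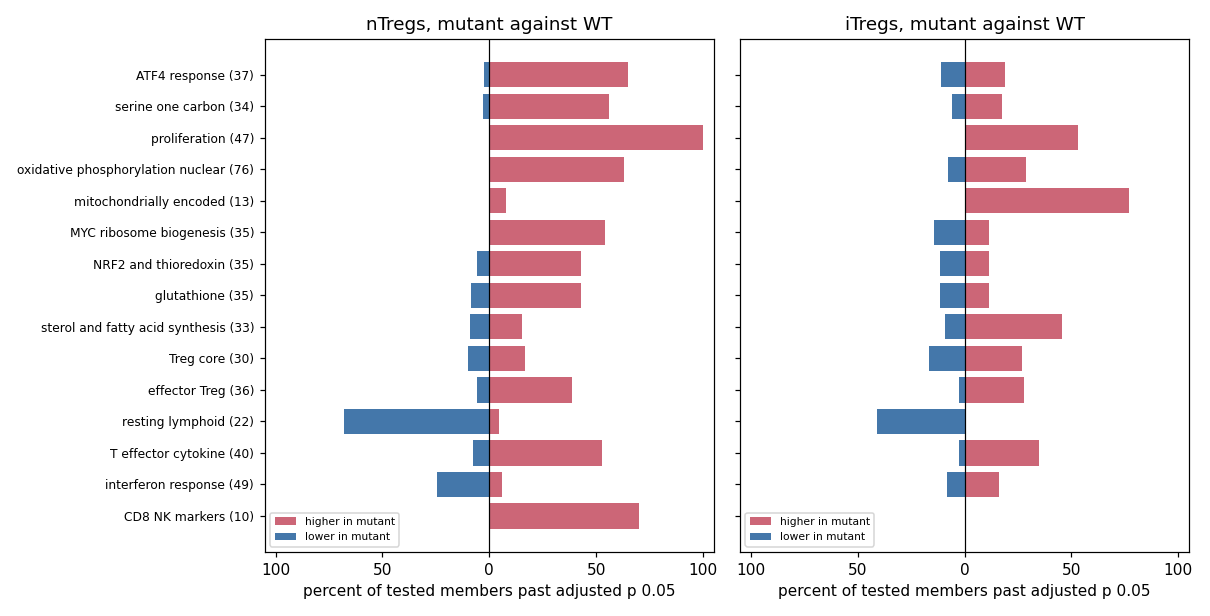
Percent of the tested genes of 15 lists (number tested in brackets) that were higher (red, right) or lower (blue, left) in the mutant at adjusted p below 0.05, for nTregs and iTregs. All 47 proliferation genes were higher in mutant nTregs, and 10 of 13 mitochondrially encoded genes were higher in mutant iTregs (3 of 13 with scaling by library size alone), and of the oxidative phosphorylation genes in iTregs, 22 were higher and 6 lower, and 8 higher and 12 lower with that scaling.

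The largest increases in mutant nTregs included 3 granzymes and a CD8 chain, and all 8 named were smaller without nTreg mutant library 1. As log2 fold change with SE, the 8 genes with the largest rise began with the granzymes Gzmk (7.13 ± 1.26), Gzma (5.12 ± 1.32) and Gzmb (4.08 ± 0.90), the co-receptor chain Cd8a (4.19 ± 0.78) and Esm1 (5.55 ± 1.19). The others were the calcium sensor Ncald (4.15 ± 0.96), the cytokine receptor Il12rb2 (3.78 ± 0.95) and the interferon-induced Ifitm1 (3.66 ± 0.51). Cd8a was at 219 CPM in nTreg mutant library 1, at 19.1 and 27.2 CPM in libraries 2 and 4 and at 3.7 to 6.36 CPM in WT, and Gzmb was at 585, 56 and 37.2 CPM against 9.36 to 16.4 CPM. Without that library all 8 still passed the test, with Gzmk at 5.18 ± 0.38, Esm1 at 3.64 ± 0.41, Gzma at 2.27 ± 0.45 and Cd8a at 2.29 ± 0.24. The values of the others were then smaller too, with Ncald at 1.74 ± 0.34, Gzmb at 1.84 ± 0.39, Il12rb2 at 1.35 ± 0.41 and Ifitm1 at 2.83 ± 0.30. The Gzma call was lost without nTreg WT library 1, 2 or 3 (adjusted p = 0.0545, 0.0621 and 0.0663). The largest falls were of the clotting factor gene F13a1 (-3.12 ± 0.38), the chemokine receptor Ccr3 (-2.46 ± 0.41), the transcription factor Sp6 (-2.42 ± 0.40), and Fbxl22 (-2.02 ± 0.29). They were followed by the kinase inhibitor Camk2n1 (-1.85 ± 0.19), the stress kinase Mapk12 (-1.84 ± 0.28), the collagen Col11a2 (-1.75 ± 0.21) and the iron exporter Slc40a1 (-1.72 ± 0.43; adjusted p = 0.0555 without nTreg WT library 2).

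Markers of other cells were present in all nTreg libraries. Of 10 CD8 T and NK cell markers, 7 were higher in the mutant (9 adjusted over the list alone; camera, adjusted p = 0.00805, and adjusted p = 0.579 with an estimated correlation) and 5 without nTreg mutant library 1. Among the 7 were Cd8b1 (2.41 ± 0.56, and 1.01 ± 0.14 without that library) and Nkg7 (2.79 ± 0.51, and 1.64 ± 0.17). Of 7 erythroid markers 2 were higher (5 adjusted over the list alone; camera, adjusted p = 0.0235, and adjusted p = 0.579 with an estimated correlation). Among 17 myeloid markers 4 were higher (3 adjusted over the list alone; camera, adjusted p = 0.523). Of 18 B cell markers 1 was higher and 2 lower (0 and 0 adjusted over the list alone; camera, adjusted p = 0.154). Of 6 plasma cell markers 1 was lower, also adjusted over the list alone (camera, adjusted p = 0.0787). With each library left out in turn, 3 (without nTreg WT library 3) to 9 CD8 and NK, 2 to 7 (without nTreg mutant library 4) erythroid and 2 (without nTreg WT library 1) to 5 myeloid markers were higher. Lower were then 1 to 9 B cell and 1 to 4 plasma cell markers, both highest without nTreg mutant library 2. The camera call of the erythroid markers was lost without nTreg WT library 3, nTreg mutant library 1 or nTreg mutant library 2 (adjusted p = 0.0721, 0.077 and 0.0671) and with scaling by library size alone (adjusted p = 0.0521). Without nTreg mutant library 1 the genes higher and lower were 26 and 0 of the ATF4 response, 19 and 1 of the serine list and 47 and 0 of proliferation. They were 41 and 0 of oxidative phosphorylation, 18 and 0 of MYC and ribosome biogenesis and 17 and 2 of glutathione. Counts were also 16 and 2 of NRF2, 2 and 16 of resting T cells, 16 and 2 of effector Tregs, 18 and 3 of T cell cytokines and effectors, 7 and 2 of the Treg core, and 15 and 5 of glycolysis. The rest were 5 and 3 of sterol synthesis, 2 and 0 of the mitochondrially encoded list, 3 and 11 of the interferon response, 10 and 5 of p53, 5 and 2 of unfolded protein, 4 and 3 of metal, and 3 and 6 of the immediate early list.

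**Figure D3:**
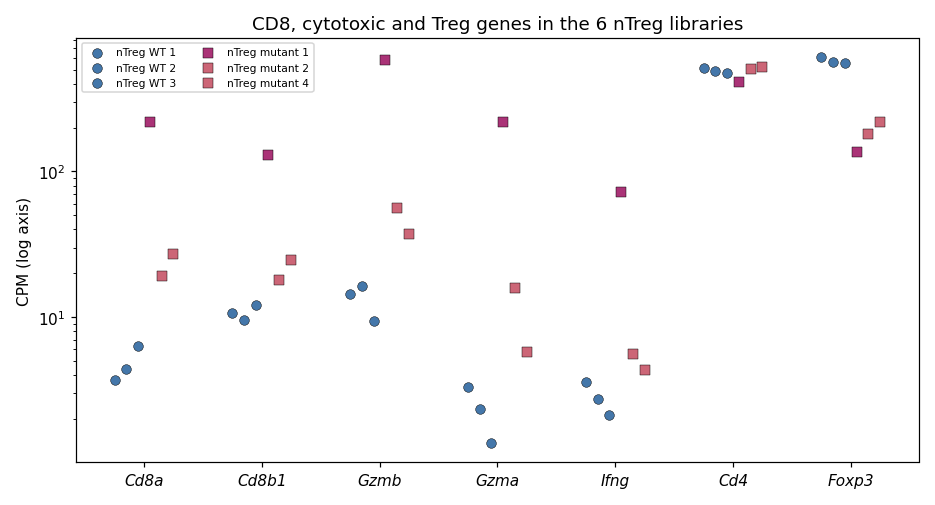
CPM (log axis) of 7 genes in the 6 nTreg libraries, WT as blue circles and mutant as squares with nTreg mutant library 1 in purple. That library had the highest Cd8a, Cd8b1, Gzmb, Gzma and Ifng and the lowest Foxp3 of the 6; Ifng and Cd4 were chosen after their values were seen.

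In all, 6269 of 17977 tested genes differed between mutant and WT nTregs, 3471 higher and 2798 lower (edgeR, adjusted p below 0.05), of which 1031 and 284 changed at least 2-fold. The higher share was 55.4% of these calls and 65.4% with scaling by library size alone.

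The same comparison in iTregs asks what the mutation does in cells differentiated outside the animal. Foxp3 fell there as well, from 293 ± 6.89 to 92.9 ± 15.9 CPM (log2 fold change -1.66 ± 0.15, adjusted p = 0.000188). Of the serine genes, Psat1 rose by 0.38 ± 0.09 (adjusted p = 0.0107, and 0.0613 without iTreg WT library 1) and Shmt2 fell by 0.49 (adjusted p = 0.00661). Phgdh (0.03 ± 0.07, adjusted p = 0.808), Shmt1 (0.21 ± 0.12, adjusted p = 0.238), and Mthfd2 (0.08 ± 0.09, adjusted p = 0.51) did not pass the test. Neither did Slc1a4 (-0.32 ± 0.18, adjusted p = 0.217), Slc1a5 (-0.13 ± 0.07, adjusted p = 0.194), Gclm (0.01 ± 0.14, adjusted p = 0.999) and Gss (0.05 ± 0.12, adjusted p = 0.8). Of 34 serine and one-carbon genes 6 rose and 2 fell, also adjusted over the list alone, and 4 and 4 with scaling by library size alone (camera, adjusted p = 0.837). Of 37 ATF4-response genes 7 rose and 4 fell (7 and 5 adjusted over the list alone; camera, adjusted p = 0.837), and 6 and 7 with that scaling. The stress-induced Nupr1 rose by 1.14 ± 0.19. Of 35 glutathione genes 4 rose and 4 fell, also adjusted over the list alone, and 4 and 5 with that scaling (camera, adjusted p = 0.981). Glo1, which detoxifies methylglyoxal using glutathione, rose by 0.40 ± 0.06. Of 35 NRF2 genes 4 rose and 4 fell (8 and 4 adjusted over the list alone; camera, adjusted p = 0.837), and 2 and 6 with that scaling. The ferritin chain Ftl1 changed by -0.60 ± 0.10. Without iTreg WT library 1 the genes that rose were 2 of the serine list, 3 of the ATF4 response, 1 of glutathione and 2 of NRF2. Without nTreg mutant library 1 they were 10, 8, 5 and 10, with 4, 10, 7 and 6 that fell. The spread of a gene was estimated over all 4 groups, so an nTreg library bears on iTreg calls.

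Sterol and fatty acid genes rose in mutant iTregs, 15 of 33 against 3 that fell (15 and 4 adjusted over the list alone; camera, adjusted p = 0.00244). The fatty acid desaturases Scd1 and Scd2 rose by 1.81 ± 0.28 and 1.02 ± 0.17, and Cyp51 of sterol synthesis by 0.44 ± 0.07. Of the 13 mitochondrially encoded genes 10 rose and 0 fell (13 and 0 adjusted over the list alone; camera, adjusted p = 0.000561), and 3 and 0 with scaling by library size alone. Genes of the mitochondrial genome held 6.02% and 5.8% of counts in iTreg mutant libraries 1 and 2, but 4.66% in library 4, within the 4.31% to 4.94% of WT. The respiratory chain gene mt-Cytb rose by 0.60 ± 0.12. Of 76 nuclear oxidative phosphorylation genes 22 rose and 6 fell (31 and 8 adjusted over the list alone; camera, adjusted p = 0.0211), but 8 rose and 12 fell with scaling by library size alone. Of 47 proliferation genes 25 rose and 0 fell (30 and 0 adjusted over the list alone; camera, adjusted p = 1.34e-06). The spindle gene Hmmr rose by 1.03 ± 0.21. Of 25 unfolded-protein genes 7 rose and 1 fell (10 and 1 adjusted over the list alone; camera, adjusted p = 0.00922). The signal peptidase gene Sec11c rose by 0.73 ± 0.08. Each of these camera calls was lost with the correlation taken from the data (adjusted p = 0.985 with an estimated correlation, for each list). The call of oxidative phosphorylation was also lost without iTreg WT library 2 (adjusted p = 0.0885) or iTreg mutant library 4 (adjusted p = 0.224), and with scaling by library size alone (adjusted p = 0.0536). Without iTreg WT library 1 the genes that rose were 1 of proliferation, 2 of oxidative phosphorylation, 1 of the mitochondrially encoded list, 2 of unfolded protein and 11 of sterol synthesis. Without nTreg mutant library 1 the genes that rose and fell were 36 and 2 of proliferation, 33 and 12 of oxidative phosphorylation and 14 and 2 of unfolded protein.

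T cell identity genes changed in iTregs as follows. Klf2, a resting gene that keeps T cells circulating through lymph nodes, fell by 1.27. Of the 22 resting genes 9 fell and 0 rose, also adjusted over the list alone (camera, adjusted p = 0.000533). The chemokine receptor Ccr6 and the adhesion receptor Cd44 rose by 0.95 ± 0.20 and 0.64 ± 0.13. Of 36 effector Treg genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera, adjusted p = 0.00244). Of 40 cytokine and effector genes 14 rose and 1 fell (18 and 1 adjusted over the list alone; camera, adjusted p = 0.000554). The cytokine genes rose, Il9 from 4.4 ± 1.39 to 13.8 ± 3.78 CPM, Il17f from 32.1 ± 4.14 to 69.1 ± 21.6 CPM and Il17a from 0.331 ± 0.14 to 1.73 ± 0.80 CPM. Of 30 Treg core genes 8 rose and 5 fell (9 and 6 adjusted over the list alone; camera, adjusted p = 0.837), and 6 and 6 with scaling by library size alone. The inhibitory receptor Tigit rose from 2.27 ± 0.12 to 6.25 ± 0.33 CPM, and Lrrc32, which holds latent TGF-beta at the surface, fell by 0.80. The camera calls of the resting, effector Treg and cytokine lists were lost with the correlation taken from the data (adjusted p = 0.985 with an estimated correlation, for each). Without iTreg WT library 1, 7 resting genes fell, and 4 effector Treg, 5 cytokine and 2 Treg core genes rose. Without nTreg mutant library 1, 15 resting genes fell, and 15 effector Treg, 21 cytokine and 9 Treg core genes rose.

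The other lists did not pass camera in iTregs. Of 49 interferon-response genes 8 rose and 4 fell (8 and 3 adjusted over the list alone; camera, adjusted p = 0.881). The chaperone gene Rtp4 rose by 0.87 ± 0.15. Of 27 p53-response genes 10 rose and 1 fell (13 and 2 adjusted over the list alone; camera, adjusted p = 0.102). The p53 target Perp rose by 1.89 ± 0.39. Of 36 glycolysis and hypoxia genes 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera, adjusted p = 0.837). Of 16 metal genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera, adjusted p = 0.764), and 1 and 1 with scaling by library size alone. Of 35 MYC and ribosome genes 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera, adjusted p = 0.881). Of 28 immediate early genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera, adjusted p = 0.881), and 4 and 5 with that scaling. Of the markers of other cells, 3 of 18 B cell markers rose and 1 fell (3 and 1 adjusted over the list alone; camera, adjusted p = 0.132). Among 6 plasma cell markers 1 rose (0 adjusted over the list alone; camera, adjusted p = 0.48). Among 17 myeloid markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.981). No CD8 and NK marker passed of 10, the smallest p being that of Crtam (0.44 ± 0.39, adjusted p = 0.427). No erythroid marker passed of 7. This held over all genes and adjusted over the list alone (camera, adjusted p = 0.881 for both lists). Over the libraries left out in turn, the genes that rose and those that fell were 4 to 9 and 1 to 5 of the interferon response, 4 to 12 and 0 to 4 of p53, 1 to 10 and 1 to 6 of glycolysis, and 0 to 8 and 2 to 8 of MYC and ribosome biogenesis. They were 1 to 3 and 1 to 2 of metal, 2 to 5 and 1 to 6 of the immediate early list, 1 to 4 and 0 to 1 of B cell, 0 to 2 and 0 of plasma cell, and 0 to 2 and 0 to 1 of myeloid markers.

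The largest rises in mutant iTregs were of the growth cone gene Gap43 (3.44 ± 0.35), the enkephalin precursor Penk (3.18 ± 0.45), the actin-severing Scin (2.67 ± 0.60), and the fatty acid receptor Cd36 (2.67 ± 0.43). Next came the semaphorin Sema6d (2.48 ± 0.53), the interferon-induced GTPase Iigp1 (2.35 ± 0.51), the gap junction gene Gja5 (2.21 ± 0.34) and Ly6a (2.20 ± 0.64). Single libraries stood out in some of these. Scin, Penk and Sema6d were at 27.7, 14.5 and 11.6 CPM in iTreg mutant library 4, and at most at 5.77, 4.79 and 3.33 CPM in libraries 1 and 2. Iigp1 was at 46 CPM in iTreg mutant library 1 and at 15.1 and 9.23 CPM in libraries 2 and 4. The Ly6a call was lost without iTreg WT library 1, iTreg WT library 2 or iTreg mutant library 1 (adjusted p = 0.101, 0.0776 and 0.123). The largest falls besides Foxp3 were of the oxidoreductase Pyroxd2 (-2.85 ± 0.40), Xkrx (-1.87 ± 0.31), the transcription factor Pou6f1 (-1.83 ± 0.27) and the activin-type receptor Acvr1c (-1.76 ± 0.39). Smaller were those of the Rap activator Rasgrp2 (-1.64 ± 0.17), the neuropeptide receptor Vipr1 (-1.6 ± 0.22) and Ncmap (-1.55 ± 0.32). In all, 4561 of 17977 genes differed, 2517 higher and 2044 lower, of which 418 and 237 changed at least 2-fold. The number fell to 1770 without iTreg WT library 1, 2039 without iTreg WT library 2, 2340 without iTreg mutant library 1 and 2848 without iTreg mutant library 2. The higher share was 55.2%, against 35.5% with scaling by library size alone.

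Whether the mutation acted differently in the 2 kinds of Treg was tested as the nTreg effect minus the iTreg effect. Larger and smaller effect, here and below, refer to the signed log2 fold change and not to its size. Part of the ATF4-response and serine lists differed. Of 37 ATF4-response genes 18 had the larger effect in nTregs and 0 the smaller (22 and 0 adjusted over the list alone; camera, adjusted p = 2.83e-09, and adjusted p = 0.391 with an estimated correlation). Among 34 serine genes the split was 11 against 1 (16 and 1 adjusted over the list alone; camera, adjusted p = 0.000581, and adjusted p = 0.392 with an estimated correlation). The difference was 2.53 ± 0.21 for Asns (adjusted p = 0.000292), 2.24 ± 0.30 for Slc1a4, and 1.32 ± 0.15 for Shmt2. It was 0.85 ± 0.12 for Mthfd2, 0.78 ± 0.10 for Phgdh, 0.65 ± 0.13 for Psat1 and 0.74 ± 0.18 for Shmt1 (adjusted p = 0.0191, and 0.0515 without iTreg mutant library 1). The difference did not pass for Gss (0.55 ± 0.18, adjusted p = 0.0584), Gclm (0.49 ± 0.20, adjusted p = 0.121), Slc1a5 (-0.02 ± 0.10, adjusted p = 0.926) or Foxp3 (-0.04 ± 0.21, adjusted p = 0.933). Gclc itself fell less in nTregs, by a difference of 0.65 ± 0.10 (adjusted p = 0.00381). With each library left out in turn, 15 to 22 ATF4-response genes had the larger effect in nTregs, and 6 (without iTreg mutant library 1) to 18 (without nTreg mutant library 1) serine genes.

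**Figure D4:**
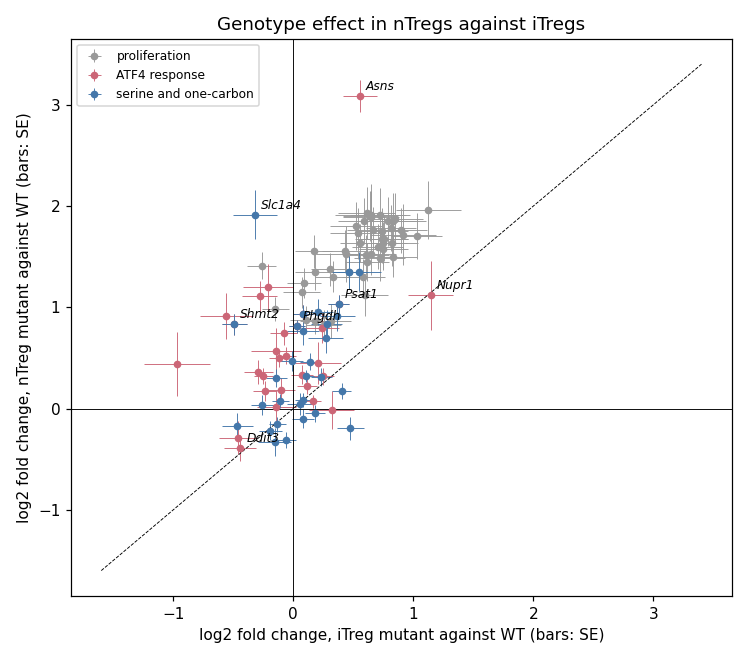
Log2 fold change of mutant against WT with its SE in nTregs (vertical) against iTregs (horizontal) for proliferation (grey), ATF4-response (red) and serine and one-carbon genes (blue, also for genes on both lists) with a mean of at least 5 CPM in a group; on the dashed line both effects are equal. Asns lies at 3.09 in nTregs and 0.55 in iTregs, and Shmt2 at 0.83 and -0.49.

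Of 47 proliferation genes 24 rose more in nTregs and 0 less (44 and 0 adjusted over the list alone; camera, adjusted p = 5.59e-14, and adjusted p = 0.681 with an estimated correlation). E2f1 differed by 1.67 ± 0.18. The larger effect was in nTregs for 10 of 35 MYC and ribosome genes against 0 (14 and 0 adjusted over the list alone; camera, adjusted p = 4.71e-05, and adjusted p = 0.681 with an estimated correlation). So it was for 14 of 76 oxidative phosphorylation genes against 1 (22 and 1 adjusted over the list alone; camera, adjusted p = 0.000389, and adjusted p = 0.745 with an estimated correlation). Among 35 NRF2 genes the split was 7 against 1 (7 and 2 adjusted over the list alone; camera, adjusted p = 0.0114, and adjusted p = 0.681 with an estimated correlation). Ftl1 (difference 0.85) was among the 7, though it fell in iTregs and did not pass in nTregs (0.25, adjusted p = 0.0761). The effect was smaller in nTregs for 5 of 13 mitochondrially encoded genes against 0 (8 and 0 adjusted over the list alone; camera, adjusted p = 0.00174, and adjusted p = 0.681 with an estimated correlation). Of 33 sterol and fatty acid genes 3 had the smaller and 2 the larger effect in nTregs, 2 and 3 with scaling by library size alone (8 and 3 adjusted over the list alone; camera, adjusted p = 0.0212, and adjusted p = 0.745 with an estimated correlation). Scd1 differed by -2.32 ± 0.39. Of the markers of other cells, 1 of 10 of CD8 and NK cells had the larger effect in nTregs (Nkg7, 2.68 ± 0.70, lost without any of 7 single libraries, highest adjusted p = 0.0702, without iTreg mutant library 2), 1 of 18 of B cells the smaller, and none of erythroid or plasma cells passed (1, 1, 0 and 2 adjusted over the list alone, the 2 lower). Below 1 CPM in both iTreg groups were 4 of the 10 CD8 and NK, 11 of 18 B cell, 7 of 7 erythroid and 4 of 6 plasma cell markers, so for these genes the difference rests on little or no iTreg expression. The list tests were therefore repeated on genes at 1 CPM or more in both cell types, a choice made after seeing the data. The 8 lists above kept their camera calls (adjusted p = 2.85e-13 to 0.0368, and adjusted p = 0.5 to 0.725 with an estimated correlation). CD8 and NK markers (adjusted p = 0.0502) and B cell markers (adjusted p = 0.0653) did not pass, and too few erythroid and plasma cell markers were left to test. The other 12 of 24 lists did not pass camera. Leaving out 1 library at a time, the larger effect was in nTregs for 11 (without nTreg WT library 3) to 34 proliferation, 6 (without any of 6 single libraries) to 12 MYC and ribosome, 6 (without any of 3) to 23 (without nTreg mutant library 1) oxidative phosphorylation and 2 (without any of 5) to 9 NRF2 genes. The smaller effect was there for 0 (without any of 6) to 8 mitochondrially encoded and 2 to 8 (without iTreg WT library 3) sterol genes. The camera call was lost for sterol genes without nTreg WT library 3, nTreg mutant library 4, iTreg WT library 2 or iTreg mutant library 1 (adjusted p = 0.0683, 0.0794, 0.0622 and 0.0643).

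The genes with the largest positive difference, by a rule that asked for 5 CPM in a group, were Fbxo2, Ggt1 (3.93 ± 1.08), Adam11 (3.58 ± 0.76), Ifitm1 (3.46 ± 0.76) and Cdkn1a (2.72 ± 0.34). Fbxo2 had no count in WT nTregs and 0.0895 CPM in mutant nTregs, against 5.01 and 3.2 CPM in iTregs, so its difference has no measured size. The call of Fbxo2 was lost without any of 8 single libraries (highest adjusted p = 0.0802, without nTreg WT library 2), and that of Ggt1 without any of 7 (highest 0.0889, without iTreg WT library 3). Ggt1 was at 11 CPM in nTreg mutant library 1 against 2.58 and 1.67 CPM in libraries 2 and 4, and its change in nTregs was 1.94 ± 0.57 without that library, against 3.14 with it. Below 1 CPM in both iTreg groups were Adam11 and Ifitm1. The largest negative differences were of Abi3bp (-3.59 ± 0.58), Bcar3 (-3.57 ± 0.73), Gja5 (-3.48 ± 0.90), F13a1 (-3.44 ± 0.62) and Cd36 (-3.27 ± 0.58), and the Gja5 call was lost without nTreg WT library 3 (adjusted p = 0.115) or nTreg mutant library 2 (adjusted p = 0.0652). Abi3bp, Bcar3 and F13a1 were below 1 CPM in both iTreg groups and Gja5 in both nTreg groups. In all, 2392 of 17977 genes passed, 1291 with a positive and 1101 with a negative difference. The number was 1209 without nTreg WT library 1, 1104 without nTreg WT library 2, 1376 and 1247 without iTreg WT libraries 1 and 2, and 1287 and 1298 without iTreg mutant libraries 1 and 2. The positive share was 54%, against 82.2% with scaling by library size alone, which moved the median over all genes from 0.003 to 0.138 (log2).

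The 2 genotype comparisons share no library, but the spread of each gene was estimated over all 4 groups for both. Their calls are therefore not independent, and the expected numbers are no exact measure of what unrelated effects would give. Of the genes called in each, 1043 were higher in both (486 expected of independent lists) and 749 lower in both (318.1 expected), while 131 and 120 went opposite ways (394.7 and 391.8 expected). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.34.

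The WT iTregs and nTregs give the background of both comparisons. iTregs had more of the growth and metabolic programmes. All 47 proliferation genes, 33 of 35 MYC and ribosome genes (0 lower), 61 of 76 oxidative phosphorylation genes (0 lower) and 24 of 33 sterol genes (1 lower) were higher in iTregs. So were 26 of 34 serine genes (2 lower) and 29 of 37 ATF4-response genes (3 lower). Phgdh was higher by 1.31 ± 0.07, Slc1a4 by 3.98 ± 0.23 and Cdkn1a by 5.90 ± 0.28. These counts were the same adjusted over the list alone, except 25 for sterol genes. Foxp3 was lower in iTregs (-0.98 ± 0.15), as was Gclc (-0.50 ± 0.07). Of the Treg core genes 19 of 30 were lower and 7 higher, with Tigit at -4.70 ± 0.12 and Ikzf2 at -4.98 ± 0.37. Of 36 effector Treg genes 22 were lower and 7 higher. Of 49 interferon-response genes 47 were lower and 0 higher, with Ifi213 at -7.10 ± 0.12. The camera test passed for each of these lists (adjusted p from 1.26e-16 for the interferon response to 0.00883 for the Treg core genes). It passed for none with the correlation taken from the data (adjusted p = 0.157 for the interferon response and adjusted p = 0.389 for the Treg core genes with an estimated correlation).

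Markers of B cells, plasma cells, erythroid cells and myeloid cells were far lower in iTregs. The numbers lower were 18 of 18, 6 of 6, 6 of 7 and 15 of 17, with 1 myeloid marker higher (the same adjusted over the list alone; camera, adjusted p = 2.59e-11, 0.000418, 0.00105 and 6.69e-05; adjusted p = 0.157, 0.312, 0.35 and 0.157 with an estimated correlation). Of 10 CD8 and NK markers 4 were lower and 1 higher (camera, adjusted p = 0.206). Of 27 p53-response genes 20 were higher and 6 lower (camera, adjusted p = 0.00105, and adjusted p = 0.35 with an estimated correlation). Of 36 glycolysis and hypoxia genes 21 were higher and 4 lower (camera, adjusted p = 0.00854, and adjusted p = 0.389 with an estimated correlation). Higher and lower genes were 14 and 13 of 35 for glutathione (11 and 13 with scaling by library size alone), 16 and 11 of 35 for NRF2 and 3 and 2 of 13 for the mitochondrially encoded list (2 and 2 adjusted over the list alone, and 3 and 4 with that scaling). They were 6 and 11 of 22 for resting T cells, 17 and 13 of 40 for cytokines, 8 and 5 of 16 for metals, 7 and 9 of 25 for unfolded protein and 12 and 7 of 28 for immediate early genes. Apart from the mitochondrial list their counts were the same adjusted over the list alone, and from glutathione on the camera test did not pass.

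The largest rises in iTregs were of Pdpn and Fbxo2, which had no count in WT nTregs and were at least 233-fold and 153-fold higher, the xenobiotic enzyme Cyp1a1 (8.30 ± 0.35), and Il17f (8.15 ± 0.40). Next were the enzyme genes Akr1c18 (7.74 ± 0.30), Acsl6 (7.28 ± 0.39), and Bdh2 (6.53 ± 0.29) and the transporter Slc4a11 (6.40 ± 0.24). The 8 largest falls were of genes with no count in WT iTregs, so that each fold is a lower bound against 3 counts over the group. The haemoglobin genes Hbb-bs and Hbb-bt were at least 2030-fold and 1770-fold lower. The B cell genes Cd22, Cr2, Pax5 and Iglc2 were at least 2020-fold, 1870-fold, 1780-fold and 1170-fold lower. Klrg1, a gene of the effector Treg list, was at least 1860-fold lower and Cybb of phagocytes at least 1760-fold. In all, 12486 of 17977 genes differed, 6066 higher and 6420 lower in iTregs.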

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

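The split counts, the test of the ATF4 response without nTreg mutant library 1 and the gene lists were set before their results were seen, while the tests on CD8 markers, on Foxp3, on cycling cells and on genes expressed in both cell types were chosen after. What drew attention to the values in this paragraph and the next is a genotype effect that differed between nTregs and iTregs by the tested difference (nTreg effect minus iTreg effect, log2, adjusted p below 0.05, 3 libraries in each of 4 groups). It did so for 2392 of the 17977 tested genes and for 51 of the 118 genes named in the report, 30 with a larger and 21 with a smaller value in nTregs. Some of the 118 were named because of this difference, so their share does not measure how common it was. Of 60 splits drawn from the 200 possible, 2 gave at least 2392 genes, the real one included, and the highest other gave 3120. That other split kept the nTreg genotypes and regrouped the iTregs, so it carried the nTreg effect too. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes, with 6269 in nTregs, 4561 in iTregs and 12486 between WT cells, against a highest other of 0. Each other split mixed libraries of the compared groups, so real differences counted as spread within a group. Their 0 is therefore no measure of what unrelated groupings give.

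Positive differences were those of Fbxo2 (5.2, which depends on the prior count because WT nTregs had no count), Ggt1 (3.93), Adam11 (3.58), Ifitm1 (3.46), Cdkn1a (2.72), Nkg7 (2.68), Asns (2.53), Slc1a4 (2.24), E2f1 (1.67), Pou6f1 (1.57), Uhrf1 (1.38), Shmt2 (1.32), Rasgrp2 (1.16), Mcm3 (1.15), Hk2 (0.99), Klf2 (0.94), Lag3 (0.91), Atp5g1 (0.9), Tyms (0.88), Srm (0.86), Lrrc32 (0.86), Ftl1 (0.85), Mthfd2 (0.85), Phgdh (0.78), Txn1 (0.78), Shmt1 (0.74), Gclc (0.65), Psat1 (0.65), Cox6a1 (0.41) and Sod1 (0.36). Negative ones were those of Glo1 (-0.35), mt-Cytb (-0.64), Pdk1 (-0.76), Ifi213 (-0.79), Foxo1 (-0.79), Ifi206 (-0.91), Rtp4 (-1.03), Ccr6 (-1.06), P4ha1 (-1.14), Tigit (-1.2), Sesn1 (-1.34), Camk2n1 (-1.56), Fbxl22 (-1.69), Penk (-2.26), Sp6 (-2.32), Scd1 (-2.32), Cd36 (-3.27), F13a1 (-3.44), Gja5 (-3.48), Bcar3 (-3.57) and Abi3bp (-3.59). The Lag3 call was lost without nTreg WT library 1 (adjusted p = 0.0537) or iTreg WT library 2 (adjusted p = 0.0545). That of Lrrc32 was lost without nTreg WT library 2 (0.0531), and that of Penk without nTreg WT library 2 (0.053) or iTreg WT library 2 (0.0635). Shmt1 was lost without iTreg mutant library 1 (0.0515), and Gja5 without nTreg WT library 3 (0.115) or nTreg mutant library 2 (0.0652). Each of the following calls was lost without any of 4 to 10 single libraries, at a highest adjusted p of 0.0631 for Glo1 and 0.0765 for Ccr6 (both without nTreg WT library 2), 0.0604 for Tyms (iTreg WT library 3), 0.0707 for mt-Cytb (iTreg WT library 2), 0.0838 for Sp6 (iTreg mutant library 4), 0.0772 for Cox6a1 (nTreg WT library 2), 0.0702 for Nkg7 (iTreg mutant library 2), 0.0934 for Txn1 (iTreg mutant library 2), 0.0983 for Sod1 (nTreg WT library 2), 0.11 for Hk2 (nTreg WT library 1), 0.135 for Fbxl22 (iTreg mutant library 2) and 0.0802 for Fbxo2 (nTreg WT library 2). The same held of Ggt1 (0.0889, iTreg WT library 3). With library size alone the calls of Glo1 (adjusted p = 0.102), Ccr6 (0.0526) and Fbxl22 (0.0628) were lost, with RLE scaling that of Fbxl22 (0.0529), with the filter of 1 CPM that of Fbxl22 (0.0525), and with no filter those of Glo1 (0.0744) and Sod1 (0.0552). With the replicate number as a block Tyms, Sod1, Txn1, Hk2, Nkg7, Glo1, Fbxl22, Penk and Fbxo2 were lost (adjusted p = 0.0513 to 0.0889). With genotype and number as the block Tyms, Sod1, Txn1, Cox6a1, Hk2, Glo1, Penk and Fbxo2 were lost (adjusted p = 0.0552 to 0.0835). Of 24 lists, 12 passed camera for the difference, 8 of them also on genes at 1 CPM or more in both cell types: proliferation (adjusted p = 5.59e-14), ATF4 response (2.83e-09), MYC and ribosome biogenesis (4.71e-05), oxidative phosphorylation (0.000389), serine and one-carbon (0.000581), mitochondrially encoded (0.00174), NRF2 (0.0114) and sterol synthesis (0.0212). The B cell (0.0095), plasma cell (0.0122), CD8 and NK (0.0209) and erythroid markers (0.0209) are not counted as differing, as 11 of 18, 4 of 6, 4 of 10 and 7 of 7 were below 1 CPM in both iTreg groups. Among genes at 1 CPM or more in both cell types the B cell (adjusted p = 0.0653) and CD8 and NK markers (0.0502) did not pass, and the others were too few. None of the 12 passed with an estimated correlation (adjusted p = 0.391 to 0.745).

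CD8 and cytotoxic genes stood apart in nTreg mutant library 1 when its values were seen beside the others: 9 of the 10 CD8 and NK markers were highest there among the 3 mutant libraries, and Cd8a reached 219 CPM against 19.1 and 27.2 CPM. A lower Treg share that raises every other cell type would raise the B cell markers too, and these were not raised. Their median log2 ratio to the other 2 libraries was -0.63 (-0.78 to -0.35), and 0 of 18 were highest there. The interval covers the spread between genes, not between libraries. With 1 library against 2, this cannot tell a lower Treg share from B cell content that varies between libraries. CD8 T or NK cells carried into that library cannot be told apart from expression by the mutant Tregs themselves, because the marker count restates what was seen. Libraries 2 and 4 also lay above WT for Cd8a. Of the cytotoxic and effector genes with the largest rises in nTregs, Gzmb and Il12rb2 were also higher in mutant than in WT iTregs. Gzmb was at 19.6 to 33.7 CPM against 2.42 to 9.65 CPM, and Il12rb2 at 11.3 to 16.7 CPM against 3.26 to 6.32 CPM. Gzmk, Gzma and Esm1 had no count in iTregs. How the cells were sorted, and whether a gate would remove CD8 cells, was not analysed here.

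Foxp3, weighed because it fell in mutant nTregs and iTregs alike, had no difference past the threshold between them (adjusted p = 0.933). Dilution of the mutant nTregs by other cells as the whole of the fall is argued against by the other 29 Treg core genes. Their median log2 fold change was 0.06 (-0.08 to 0.16) against -1.70 for Foxp3. The list mixed genes that rose (5 of 30) with genes that fell (3, Foxp3 among them), so its median does not exclude a smaller part played by dilution. Scaling is argued against by the Foxp3 value nearest 0 over the scalings, -1.65. An altered Foxp3 allele carried only by the mutants cannot be told apart from regulation: the difference between the cell types, -0.04 (-0.53 to 0.44), allows both. An effect of Gclc loss on Foxp3 stays open, and reads over the gene were not used here.

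In the ATF4-response list 18 of 37 genes and in the serine list 11 of 34 had the higher log2 change in nTregs. Neither list passed camera with an estimated correlation (adjusted p = 0.391 and 0.392), though both passed the directional test of fry (adjusted p = 0.00164 and 0.00335). The library bearing CD8 genes as the only source is argued against, since 23 of 25 ATF4-response calls kept their direction without it. A larger share of cycling cells cannot be told apart from a response within cells, as only 1 gene of the ATF4 response at 5 CPM or more, Asns, rose past the most raised proliferation gene by over 2 SE, and the medians were 0.69 and 1.6. Whether nTregs depend on Gclc in another way than cultured cells stays open, as culture and cell origin go together in this design.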

How the results depend on the processing

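The alternatives were set before the data were examined, apart from protein-coding genes alone, list counts without single libraries, and list tests on genes at 1 CPM or more in both cell types. No named gene or list test reversed its direction where either value passed, though some that passed in neither case changed sign. The split of calls did in iTregs, where genes that rose were fewer than those that fell with library size alone (1606 and 2921), a filter of 1 CPM (2041 and 2490) and without iTreg WT library 1 (773 and 997), iTreg WT library 2 (941 and 1098) or iTreg mutant library 1 (1163 and 1177). For the difference it turned without nTreg mutant library 4 (1291 and 1310) and with protein-coding genes (1123 and 1210), and between WT cells with the filter of 1 CPM (5690 and 5564). Of 81 comparison counts under alternatives, 68 stayed within 1.5 times the reported one and 13 did not. Scaling, filters, DESeq2, fits on the compared libraries and protein-coding genes gave 4715 to 6480 genes in nTregs, 4060 to 5674 in iTregs, 2259 to 3326 for the difference and 9281 to 12839 between WT cells. With the replicate number as a replicate block, 3036 genes passed in iTregs and 1471 for the difference, and 1340 for the difference with genotype and number as the block. The cause was not tested. Number 3 occurs only in WT and number 4 only in mutant libraries, so this block and the genotype overlap in part. Libraries with the same number showed no likeness (correlations of residuals from -0.064 to 0.05). Residuals from group means of 3 libraries cannot decide whether the numbers pair the samples. With a library left out, iTreg counts ran from 1770 to 6260, those for the difference from 1104 to 3216, and nTreg counts from 4488 to 6554. The lowest of each came without a library of a compared group. The highest in iTregs and for the difference came without nTreg mutant library 1. The fit estimates the spread of a gene over all 4 groups, so iTreg p-values depend on nTreg libraries too. On the iTreg libraries alone 5674 genes passed. Without nTreg mutant library 1 the share of higher genes was 61.9% in nTregs. Named genes kept their side of the threshold in 7839 alternatives, lost it in 302 and gained it in 15. List tests kept theirs in 1385, lost it in 87 and gained it in 85, and 45 of the 87 losses came with the estimated correlation. By the directional test of fry none of the 8 lists that passed camera in iTregs passed (adjusted p = 0.0528 to 0.306), and 10 of the 12 for the difference did not (adjusted p = 0.0787 to 0.214). Those of the 12 that passed fry were the ATF4 response (adjusted p = 0.00164) and serine and one-carbon (adjusted p = 0.00335). In nTregs every list that passed camera also passed fry (adjusted p = 6.59e-05 to 0.0347). Of the counts of list members higher or lower with a library left out, 341 moved by over 1.5 times and 1963 did not. Replicate block by genotype and number could not be fitted to either genotype comparison. At these depths genes changed 1.5-fold were found in 18.7% to 44.7% of simulated cases.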

Other observations

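The test of genes near Gclc was set before its result was seen, but leaving Gclc itself out of it came after. Mutant animals may carry DNA of another strain around Gclc, which could change neighbouring genes in the same direction in both kinds of Treg. Within 10 Mb of Gclc, 11 of 117 genes did so (9.4%), against 1780 of 17859 elsewhere (9.97%; odds ratio 0.94, 0.45 to 1.75, Fisher's exact two-sided p = 1). This argues against flanking DNA as a source of many such changes.

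In nTreg mutant library 1 the median log2 ratios to the other 2 mutant libraries were -0.83 (-1.38 to -0.55) for plasma cell markers, -0.5 (-1.18 to 0.28) for myeloid, 0.46 (0.18 to 0.55) for erythroid and 2.25 (1.61 to 2.79) for CD8 and NK markers. These intervals cover the spread between genes, not between libraries. No erythroid marker was highest in nTreg mutant library 1, and 5 of 17 myeloid markers were. The erythroid Hbb-bs was at 155 CPM there, between the 242 and 47.6 CPM of nTreg mutant libraries 2 and 4. Ighm, chosen after its values were seen, was at 695 to 1200 CPM in nTregs and at 39.4 to 67.6 CPM in iTregs.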
